A study of Mus musculus with 4 samples.

How the data were processed

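Total RNA was extracted with TRIzol from forelimbs of wild-type and Shh null mouse embryos. Libraries, 2 per genotype, were prepared by Illumina methods, per the protocol label. Groups were taken from the genotype label and replicate numbers from the sample titles. Per the submitters' processing notes, the processing used TopHat2 2.0.9, SAMtools, HTSeq 0.5.4p5 and edgeR 3.4.2 with genome build mm10. The role of each tool, the gene annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes, and copies of multigene families, may share reads.

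The authors deposited one signal value per gene and library, under a name that calls them normalized counts. Every value in a column was a whole multiple of the column's smallest positive value (100% of values, within a tolerance of 0.001 reads), so the whole reads were recovered by division. TMM factors recomputed from these reads with edgeR gave the deposited scale with a difference of 0%, which identifies the deposited signal as CPM, reads relative to the TMM-scaled library size. The table held 17712 genes, each with at least 2 reads over the 4 libraries. Recovered reads per library were 29620468 and 18456502 in wild type and 23206944 and 21489093 in Shh null, and 3 reads, the limit that a count of 0 allows, correspond to 0.105, 0.165, 0.124 and 0.137 CPM in the same order. The most abundant gene, Eef1a1, took 1.54% to 1.70% of the reads. Counting intervals (95%, exact binomial on the reads pooled over a group) cover counting error only.

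The second table was the authors' own comparison. It gave the log2 fold change as deposited by the authors, with p-values and false discovery rates computed by the authors, and 17689 of its 17712 names were found in the table of values; the other 23 were not used. These values are quoted only where the authors' deposited table is named.

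Genes with a value of at least 1 CPM in at least 2 of the 4 libraries were tested (13224 genes, with 4488 below the filter). Log2(CPM + 1) was fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend, R 4.3.3) with genotype as the only term, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. A fitted log2 fold change is on this scale, whereas folds are ratios of mean CPM. The median log2 fold change of all tested genes was −0.0005. The test had been fixed before the data were examined for either whole counts or normalized values, and that for normalized values applied. As alternatives, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Of these, edgeR called 176 genes higher and 148 lower, 307 of the 328 limma calls among them in the same direction.

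In all, 25 gene lists with 329 genes were written before the data were examined, covering hedgehog, posterior, anterior, 5′ Hox, proximal, ridge, FGF, BMP, WNT, retinoic acid, chondrogenic, p53, cell cycle, hypoxia, immediate early, erythroid, endothelial, myogenic, surface ectoderm, neural crest, macrophage, trunk, neural, sex-linked and reference genes; 277 of the genes were tested and 21 stood on more than 1 list. Each list was tested with camera (two-sided, preset inter-gene correlation 0.01), adjusted over the 25 lists. No set call held with an estimated correlation, and 5 lists then had an unadjusted p under 0.05. That version rests on the few residual degrees of freedom of 4 libraries, so it had little power. The camera p of the 5′ Hox list moved from 1.2e-14 to 0.015 despite an estimated correlation of −0.035. The lost set calls therefore cannot decide whether correlated genes account for the sets. Genes named in the text were fixed by a rule before the data were examined: Shh; the 12 called genes with the largest log2 fold change in each direction among those with a mean of at least 5 CPM in the higher group and non-overlapping groups, leaving out predicted genes; for each list up to 4 called members with the largest change, or the 2 members with the largest change where fewer than 2 were called; 10 limb genes (Ptch1, Gli1, Hhip, Hand2, Grem1, Hoxd13, Gli3, Pax9, Alx4 and Fgf4); and Xist and Ddx3y. Coordinates are from GENCODE mouse release M21 for the same build.

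The steps were tested on simulated data: counts drawn from the real means and library sizes, with 200 genes changed and a list of 15 other genes raised (camera p = 1.28e-13, and p = 0.0156 with an estimated correlation). In the simulated comparison of Shh null against wild type over 13235 tested genes, 47.8% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold were called in the right direction, and 14 of 13020 unchanged genes were called. The changed genes had a mean of at least 2 CPM. Their spread followed a smooth trend over expression, without scatter of single genes. The shares recovered may therefore be lower in the real data. Each gene was also drawn independently of the others. The simulated camera p-values and false calls thus do not cover genes that move together.

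Alternatives fixed before the data were examined were pseudocounts of 0.25 and 5, no filter and a filter at 5 CPM, median-ratio and quantile scaling, limma without trend, edgeR and DESeq2, replicate number as a block, each library left out in turn, a required change of 1.5-fold, and for the lists an estimated correlation, the fry test, the block, the median-ratio scaling and each library left out. Alternatives added after the data were examined were a crossed pairing of replicates, the mean erythroid level as a covariate, and the removal of genes on chromosomes X and Y. Chromosomes for that removal came from RefSeq genes of GRCm38, which placed 13189 of the 13224 tested genes.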

Results

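RNA sequencing libraries from the forelimbs of littermate mouse embryos were compared between 2 genotypes, wild type and Shh null, with 2 libraries in each group. The embryos were labelled Swiss Webster, an outbred stock, and had 33 to 35 somites. The source label and the age label give slightly different embryonic days. Shh encodes Sonic hedgehog, the signalling protein secreted from the posterior margin of the limb bud. The deposited values were TMM-scaled CPM, read counts relative to library size, and the whole reads behind them could be recovered. The libraries held 29620468 (wild type 1), 18456502 (wild type 2), 23206944 (Shh null 1) and 21489093 (Shh null 2) reads assigned to genes. A single read was worth between 0.0351 and 0.0551 CPM. Across genes, log2 values correlated at r = 0.9925 between the wild-type libraries and r = 0.9932 between the Shh null libraries, against 0.9831 to 0.9896 between the groups. Genes are not independent replicates. The design text calls the replicates technical. The libraries of a group nevertheless differed by more than sampling noise, with a chi-square of 25.45 per degree of freedom in wild type and 16.92 in Shh null. Between the groups it was 52.28 and 27.58 for wild type 1 against Shh null 1 and 2, and 23.9 and 19.41 for wild type 2. By this measure, which grows with the number of reads, wild type 2 was nearer to each Shh null library than to wild type 1. No label names separate animals, so the p-values measure only the spread between these libraries, which may be technical. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333.

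Shh itself (chromosome 5, 28456815 to 28467256, minus strand, mm10) was measured at 11.4 and 7.88 CPM in the wild-type libraries and at 3.15 and 2.42 CPM in the Shh null libraries. The means of 9.62 ± 2.47 and 2.79 ± 0.51 (SD, n = 2) CPM differed 3.45-fold, in the direction of the labels. All log2 fold changes are given on the scale of log2(CPM + 1), which understates the change of genes with low values. On this scale the change was −1.47 ± 0.21 (SE; limma, adjusted p = 0.00615). The call ended without either Shh null library, though the log2 fold change was −1.61 without Shh null 1 and −1.34 without Shh null 2. Calls over all genes also became fewer in these fits, so the loss is not particular to Shh. The labels do not describe the allele, and reads from parts of the gene outside a deletion would be counted in these values.

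Readouts of hedgehog signalling were among the steepest losses. Gli1, a transcription factor gene induced by the pathway (chromosome 10, 127329882 to 127341974), fell 52.9-fold, from 16.3 ± 0.416 to 0.307 ± 0.083 CPM (SD, n = 2; log2 fold change −3.72 ± 0.17 SE, adjusted p = 5.77e-06). The receptor gene Ptch1 fell 5.16-fold (33.7 ± 1.93 to 6.53 ± 0.853 CPM), and Hhip, which encodes a hedgehog-binding antagonist, fell 7.99-fold. Cdon (1.71-fold) and Gas1 (1.57-fold), which encode co-receptors, rose, and are named here after their values were seen. Of the 13 tested genes of the hedgehog list, 2 were called higher, 4 lower and 7 were not called. Adjusted over the list alone, 6 were higher and 4 lower. Gli3 was not called, at 140 ± 1.17 and 163 ± 2.81 CPM (adjusted p = 0.23). As a set the list did not pass in camera (adjusted p = 0.711), but did without wild type 1 (0.0208). It passed the fry test for change in either direction (adjusted p = 0.00923), which does not compare it with other genes. Its median log2 fold change of 0.14 and its mean of −0.55 had opposite signs. Camera, which compares gene-wise test statistics, gave the direction of the mean. The Hhip call ended without Shh null 1 (adjusted p = 0.0518).

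Genes of the posterior limb bud and 5′ Hox genes fell as well, Hoxd12 and Hoxd13 the furthest of the genes named here by fitted log2 fold change. Hoxd13 (chromosome 2, 74668310 to 74671599), which patterns the digits, fell 64.8-fold, from 120.4 ± 40.8 to 1.86 ± 0.363 CPM (SD, n = 2; log2 fold change −5.37 ± 0.21 SE, limma adjusted p = 4.86e-06). Hoxd12 fell 96.3-fold, from 53.4 ± 14.1 to 0.554 ± 0.331 CPM (counting interval 66.9 to 150.7), and 166.6-fold without Shh null 1. Hoxa13 fell 24.9-fold, from 12.6 ± 6.54 to 0.507 ± 0.189 CPM (counting interval 18.0 to 43.3), and 15.8-fold without wild type 1. Hoxd11 fell 5.69-fold from 125 ± 23.5 CPM. Hand2, a transcription factor gene of the posterior mesenchyme, fell 4.46-fold (54.1 ± 2.15 to 12.1 ± 2.73 CPM), and Grem1, a BMP antagonist gene of the signalling loop between mesenchyme and ridge, fell 6.16-fold (35.7 ± 3.10 to 5.80 ± 0.34 CPM). The posterior list was made of genes known for posterior expression or for dependence on Sonic hedgehog. A fall was thus partly built into its choice. Of the 21 tested posterior genes, 15 were called lower, 0 higher and 6 were not called. Adjusted over the list alone, 16 were lower and 2 higher. Besides limma, edgeR and DESeq2 also called 0 higher, and 2 were higher at an unadjusted p under 0.05 in limma. The set passed in camera (adjusted p = 2.94e-22), with adjusted p = 0.189 with an estimated correlation. Of the 10 tested 5′ HoxA and HoxD genes, 6 were called lower and 4 were not called, and 8 were lower adjusted over the list alone (camera adjusted p = 1.5e-13, and adjusted p = 0.189 with an estimated correlation). The lists share members of the HoxD cluster and are not independent of each other.

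**Figure D1:**
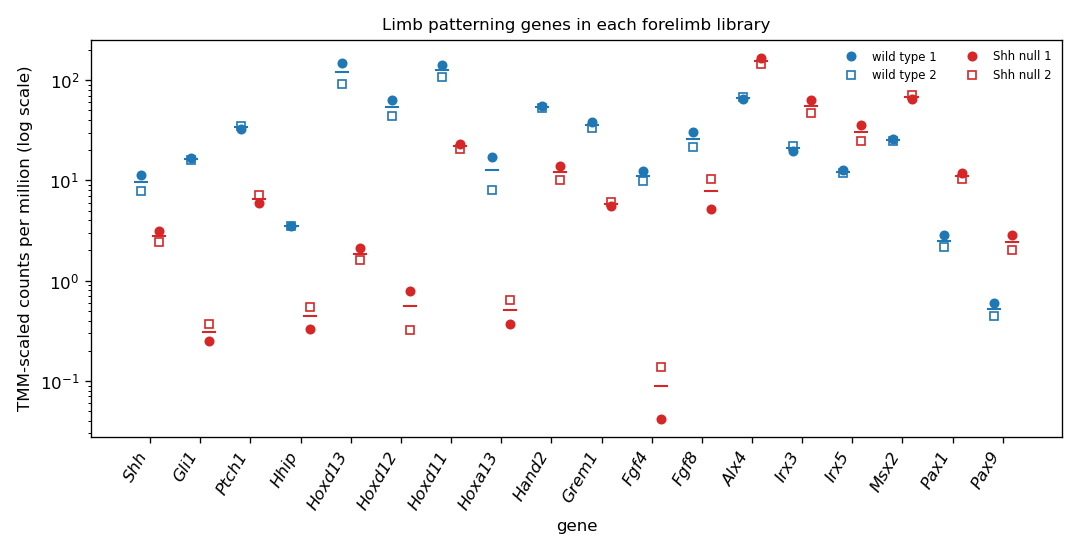
CPM in each of the 4 forelimb libraries (vertical log axis) for 18 limb patterning genes (horizontal axis), with circles for replicate 1, open squares for replicate 2 and a bar at each group mean. Hoxd13 lies at 149 and 91.5 CPM in wild type and at 2.12 and 1.60 CPM in Shh null, whereas Alx4 lies at 64.1 and 68.4 CPM in wild type and at 166 and 144 CPM in Shh null.

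In the apical ectodermal ridge, the epithelium that drives outgrowth, the ridge FGF genes were lower. Fgf4 was found in only 1 and 3 reads in the Shh null libraries, against 12.3 and 9.81 CPM in wild type, a ratio of 130.1 over the pooled reads (95% counting interval 50.5 to 479). The ratio of mean CPM was 80.5 without Shh null 1 and 266 without Shh null 2. Fgf8 fell 3.31-fold (25.8 ± 6.27 to 7.78 ± 3.62 CPM, SD, n = 2) and Fgf9 3.59-fold (7.51 ± 2.68 to 2.09 ± 0.729 CPM), while the homeobox gene Dlx3 rose 2.31-fold (2.19 ± 0.133 to 5.04 ± 0.081 CPM). Of the 14 tested ridge genes, 1 was called higher, 3 lower and 10 were not called, with 3 higher and 3 lower adjusted over the list alone, and the set did not pass in camera (adjusted p = 0.546). It passed without wild type 2 (0.0377), and in the fry test for either direction (0.00923). Of the FGF response genes, the feedback regulators Spry4 (1.93-fold), Dusp4 (1.72-fold) and Dusp6 (599 ± 31.8 to 429 ± 3.42 CPM) were called lower among 11 tested genes. The other 8 were not called, and 8 were lower adjusted over the list alone (camera adjusted p = 2.38e-05, and adjusted p = 0.211 with an estimated correlation). Without Shh null 1 the calls of Fgf8, Fgf9, Dlx3, Spry4, Dusp4 and Dusp6 ended (adjusted p = 0.114, 0.232, 0.223, 0.165, 0.0983 and 0.251). Without Shh null 2 those of Fgf9, Dlx3, Dusp4 and Dusp6 ended (0.0652, 0.114, 0.0767 and 0.134), and that of Dusp6 also ended without wild type 1 (0.107). With quantile normalization those of Dlx3 and Dusp6 ended (0.0547 and 0.11), and with the replicate block that of Dusp6 (0.07).

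Several anterior genes rose. Alx4, a homeobox gene of the anterior mesenchyme (chromosome 2, 93642384 to 93681339), rose 2.34-fold, from 66.2 ± 3.01 to 155 ± 15.8 CPM (SD, n = 2; log2 fold change 1.21 ± 0.11 SE, limma adjusted p = 0.000418). Pax1 rose 4.37-fold from 2.51 ± 0.516 CPM, Pax9 4.70-fold from 0.519 ± 0.11 CPM, Irx3 2.63-fold from 20.8 ± 1.56 CPM and Irx5 2.46-fold from 12.2 ± 0.494 CPM. The anterior list was made of genes known for anterior expression or for repression by Sonic hedgehog. A rise was thus partly built into its choice. Of the 18 tested anterior genes, 9 were called higher, 0 lower and 9 were not called. Adjusted over the list alone, 12 were higher and 1 lower. Besides limma, edgeR and DESeq2 also called 0 lower, and 1 was lower at an unadjusted p under 0.05 in limma. The set passed in camera (adjusted p = 7.53e-11), with adjusted p = 0.189 with an estimated correlation. Irx3 and Irx5 were also the 2 genes called higher among the 12 tested proximal genes. The other 10 were not called, and 6 were higher adjusted over the list alone (camera adjusted p = 0.000299, and adjusted p = 0.386 with an estimated correlation). The Irx5 call ended without Shh null 1 (adjusted p = 0.0983), and the Pax9 call ended without Shh null 1 (0.232) and without Shh null 2 (0.0707).

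Most called BMP response genes rose. Msx2 rose 2.66-fold (25.5 ± 0.816 to 67.8 ± 4.76 CPM, SD, n = 2), and Id2 and Id1, direct BMP target genes, rose 1.76-fold and 1.63-fold from 196 ± 0.604 and 121 ± 14.4 CPM. Of the 14 tested BMP genes, 5 were called higher, 1 (Grem1) lower and 8 were not called, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000503, and adjusted p = 0.386 with an estimated correlation). The WNT antagonist gene Nkd1 rose 1.69-fold (21.1 ± 0.056 to 35.5 ± 5.01 CPM) as the only 1 of 11 tested WNT response genes to be called. The other 10 were not called, and 5 were higher adjusted over the list alone (camera adjusted p = 0.000299, and adjusted p = 0.386 with an estimated correlation). Axin2 was at 41.9 ± 2.99 and 64.0 ± 10.7 CPM and was not called by limma (adjusted p = 0.050). It was called by edgeR (0.0452), by limma with the replicate block (0.0173), without wild type 1 and without wild type 2. The WNT list did not pass the fry test for either direction (0.0697). Runx2, a transcription factor gene of skeletal precursors, rose 2.43-fold (4.04 ± 0.752 to 9.83 ± 0.826 CPM) as the only called gene of 9 tested chondrogenic genes. The other 8 were not called, and 5 were higher adjusted over the list alone (camera adjusted p = 0.000264, and adjusted p = 0.386 with an estimated correlation). Gdf5 was measured at 3.05 ± 0.498 and 5.65 ± 1.39 CPM, and was called higher without wild type 1 (adjusted p = 0.0412). Without Shh null 1 the calls of Id1, Nkd1 and Runx2 ended (adjusted p = 0.207, 0.252 and 0.19). Without Shh null 2 those of Id1, Id2, Nkd1 and Runx2 ended (0.0616, 0.0555, 0.0584 and 0.0767).

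**Figure D2:**
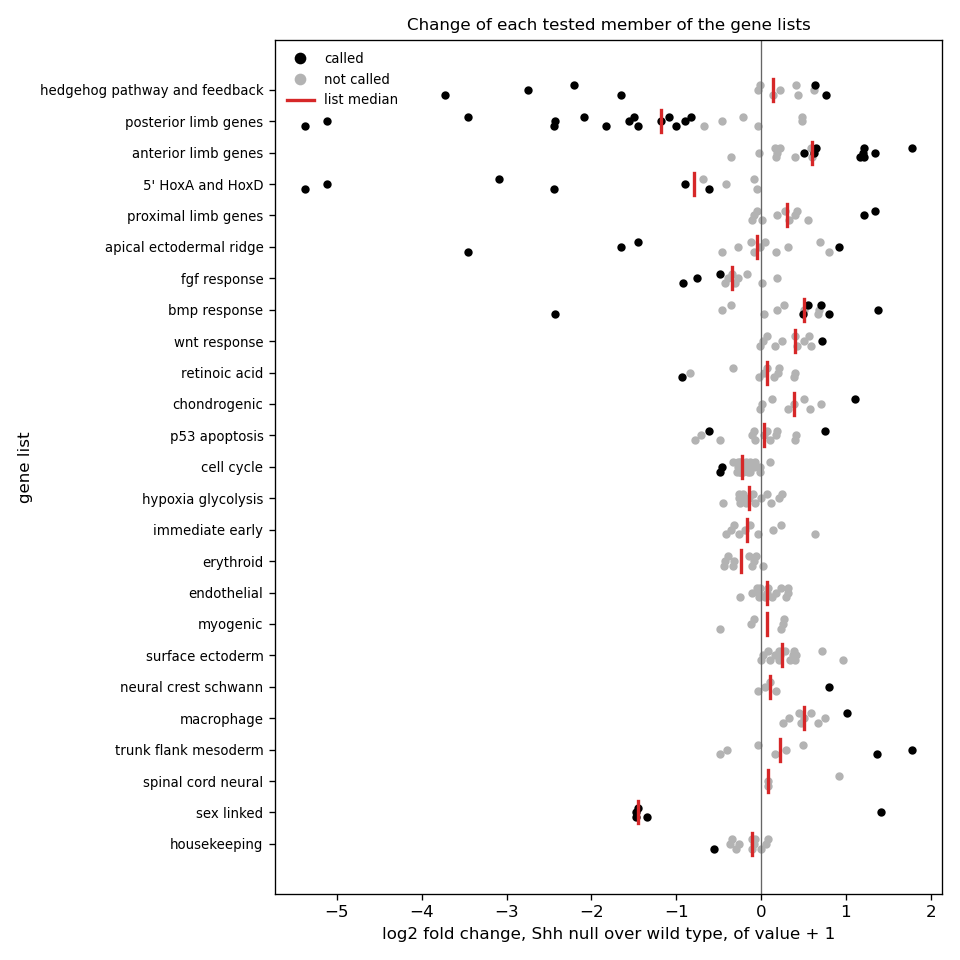
Log2 fold change of CPM + 1, Shh null over wild type (horizontal axis), for every tested member of the 25 gene lists (vertical axis), with black points for called genes, grey points for genes not called and a red bar at each list's median. The posterior list has a median of −1.17 and the anterior list a median of 0.60.

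Few genes of the other programmes were called, but few were called over all tested genes too (2.48%), so this does not mark these programmes as unchanged. Cdc6 and Ccne1, which act at the start of DNA replication, fell from 169 ± 7.85 to 121 ± 0.663 and from 127 ± 8.71 to 91.7 ± 3.92 CPM (SD, n = 2; log2 fold changes −0.48 and −0.46). Of 24 tested cell cycle genes the other 22 were not called, and 2 were lower adjusted over the list alone (camera adjusted p = 1.42e-05, and adjusted p = 0.386 with an estimated correlation). Cyp26b1, which encodes an enzyme that degrades retinoic acid, fell 1.94-fold (59.0 ± 2.01 to 30.5 ± 0.965 CPM) as the only called gene of 11 in the retinoic acid list. The other 10 were not called, with 1 higher and 1 lower adjusted over the list alone. Aldh1a2 in the same list was measured at 4.21 ± 3.08 and 1.73 ± 0.92 CPM and was not called. It was called lower with the replicate block (adjusted p = 0.0455) and without wild type 1 (log2 fold change −1.48 against −0.84). In the p53 and apoptosis list Trp53inp1 rose 1.69-fold (68.7 ± 1.66 to 116 ± 1.32 CPM) and Pmaip1 fell 1.54-fold (77.7 ± 0.599 to 50.4 ± 2.01 CPM). The other 13 of 15 tested genes were not called, with 1 higher and 3 lower adjusted over the list alone. Neither list passed in camera (adjusted p = 0.782 for retinoic acid and 0.713 for p53), and both passed the fry test for either direction (0.00923 and 0.00836). In each the median (0.07 and 0.04) and the mean (−0.06 and −0.05) of the log2 fold changes had opposite signs. Camera compares gene-wise test statistics and not log2 fold changes. Its direction had the sign of the median for retinoic acid and of the mean for p53. No gene was called by limma, edgeR or DESeq2 among 15 hypoxia and glycolysis genes (camera adjusted p = 0.175) or 10 immediate early genes (0.62), of which 0 and 0 were called adjusted over the list alone. At an unadjusted p under 0.05 in limma, 2 hypoxia and glycolysis genes were lower, and 1 immediate early gene was higher and 1 lower. The hypoxia and glycolysis set passed without wild type 1 (adjusted p = 0.0109). Hk2 (87.7 ± 17.4 and 63.6 ± 8.44 CPM) and Aldoa (511 ± 13.3 and 428 ± 17.8 CPM) had the largest differences in the first, and Fos (0.857 ± 0.277 and 1.90 ± 0.545 CPM) and Ier2 (30.5 ± 7.21 and 22.6 ± 3.41 CPM) in the other. Hk2 and Ier2 were called lower without wild type 1 (adjusted p = 0.00347 and 0.0242). Of 12 reference genes Hprt was called lower (1.47-fold, 91.8 ± 6.79 to 62.3 ± 2.54 CPM) and 11 were not, Gapdh among them (1116 ± 3.48 and 866 ± 54.3 CPM). Of the list, 2 were lower adjusted over the list alone (camera adjusted p = 0.0336, and adjusted p = 0.386 with an estimated correlation). Without Shh null 1 the calls of Cdc6, Ccne1, Hprt, Pmaip1 and Trp53inp1 ended (adjusted p = 0.23, 0.336, 0.245, 0.114 and 0.0748). Without Shh null 2 those of Cdc6, Ccne1, Hprt and Pmaip1 ended (0.115, 0.118, 0.1 and 0.0951). Cdc6 also lost its call without wild type 1 (log2 fold change −0.44) and Ccne1 without wild type 2 (−0.39). With quantile normalization the calls of Cdc6, Ccne1 and Hprt ended (adjusted p = 0.0792, 0.107 and 0.0543), and with the replicate block that of Ccne1 (0.0527). The reference list lost its set call without wild type 2 (camera adjusted p = 0.0734) and without Shh null 1 (0.25).

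Markers of other tissues were mostly not called, like most tested genes (2.48% called over all), with sex-linked genes as the exception. The Y-linked genes Ddx3y (113 ± 9.37 to 40.7 ± 2.30 CPM, SD, n = 2), Eif2s3y (54.1 ± 3.53 to 18.9 ± 0.045 CPM), Uty and Kdm5d fell between 2.59-fold and 2.87-fold, and Xist, transcribed from the inactive X chromosome, rose 2.63-fold (188 ± 52.0 to 495 ± 38.7 CPM). All 5 tested sex-linked genes were thus called, 1 higher and 4 lower and 0 not called, over all genes and adjusted over the list alone (camera adjusted p = 3.13e-05, and adjusted p = 0.386 with an estimated correlation). The macrophage gene Cx3cr1 rose 2.73-fold (1.53 ± 0.065 to 4.18 ± 1.13 CPM) and was the 1 called of 9 tested macrophage genes. The other 8 were not called, and 7 were higher adjusted over the list alone (camera adjusted p = 2.38e-05, and adjusted p = 0.211 with an estimated correlation). C1qb was measured at 0.927 ± 0.169 and 2.27 ± 0.427 CPM, and was called higher without wild type 2 (adjusted p = 0.0422). Of 8 tested trunk mesoderm genes Pax1 and Hoxb9 (4.20-fold, 0.947 ± 0.297 to 3.98 ± 0.00099 CPM) were called higher and 6 were not called, with 3 higher adjusted over the list alone. This set did not pass (camera adjusted p = 0.0558), but it passed with the replicate block (0.046) and with median-ratio scaling (0.0499). It also passed in the fry test for either direction (0.00923), and in camera without wild type 1 and without Shh null 2. Erbb3 (1.79-fold, 12.5 ± 1.54 to 22.4 ± 0.602 CPM) was the 1 gene called higher of 5 neural crest and Schwann precursor genes, both over all genes and adjusted over the list alone. The other 4, Tfap2a among them (4.45 ± 0.06 and 5.16 ± 0.504 CPM), were not called (camera adjusted p = 0.177, and 0.0229 in the fry test for either direction). Without Shh null 1 the calls of Xist, Cx3cr1, Hoxb9 and Erbb3 ended (adjusted p = 0.0819, 0.313, 0.114 and 0.221). Without Shh null 2 those of Cx3cr1, Hoxb9 and Erbb3 ended (0.0707, 0.0767 and 0.103). The Cx3cr1 call also ended with quantile normalization (0.075).

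No gene was called by limma among 16 surface ectoderm, 15 endothelial, 10 erythroid, 6 myogenic and 3 neural genes. Adjusted over the list alone, 3 surface ectoderm genes and 1 neural gene were higher and 0 endothelial, 0 erythroid and 0 myogenic genes were called. At an unadjusted p under 0.05, 7 surface ectoderm genes, 0 endothelial genes, 0 erythroid genes, 2 myogenic genes (1 higher and 1 lower) and 1 neural gene differed. By comparison, edgeR called 0 of the genes of these lists and DESeq2 called 1, a surface ectoderm gene. The surface ectoderm list passed as a set, higher in Shh null (camera adjusted p = 0.000126, and adjusted p = 0.338 with an estimated correlation). Krt15 was at 4.16 ± 2.15 and 8.83 ± 2.46 CPM and Wnt6 was at 22.7 ± 5.87 and 37.2 ± 2.86 CPM (SD, n = 2), neither called. With the replicate block both were called higher (adjusted p = 0.00758 and 0.0109). Both were also called higher without wild type 1 (log2 fold change 1.41 and 0.97). The endothelial list did not pass (camera adjusted p = 0.362) except without wild type 2 (adjusted p = 0.02), with Cldn5 at 19.1 ± 3.69 and 23.9 ± 0.241 CPM and Robo4 at 12.7 ± 0.295 and 16.4 ± 4.65 CPM. The myogenic list did not pass (0.711), with Pax3 at 13.2 ± 4.05 and 15.8 ± 0.049 CPM and Myog at 1.20 ± 0.013 and 0.583 ± 0.113 CPM. The neural list did not pass (0.177), with Isl1 at 1.44 ± 0.246 and 3.68 ± 1.19 CPM and Stmn2 at 1.55 ± 0.151 and 1.71 ± 0.281 CPM. Isl1 was called higher with the replicate block (adjusted p = 0.0207), without wild type 1 and without wild type 2. Erythroid RNA differed mainly within groups. The 10 erythroid genes were between 2.76-fold and 4.52-fold higher in wild type 1 than in wild type 2 and between 1.27-fold and 1.90-fold higher in Shh null 2 than in Shh null 1. Klf1 was at 24.2, 5.34, 7.34 and 9.38 CPM in the order wild type 1, wild type 2, Shh null 1 and Shh null 2, and was called lower without wild type 2 (adjusted p = 1.4e-06). The erythroid list did not pass (camera adjusted p = 0.396). It turned higher in Shh null without wild type 1 and stayed lower without wild type 2. Its genes moved together, with an estimated inter-gene correlation of 0.988 against the preset 0.01. Camera p-values of this list with the preset therefore overstate the evidence, and these turns are not evidence of a genotype change.

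**Figure D3:**
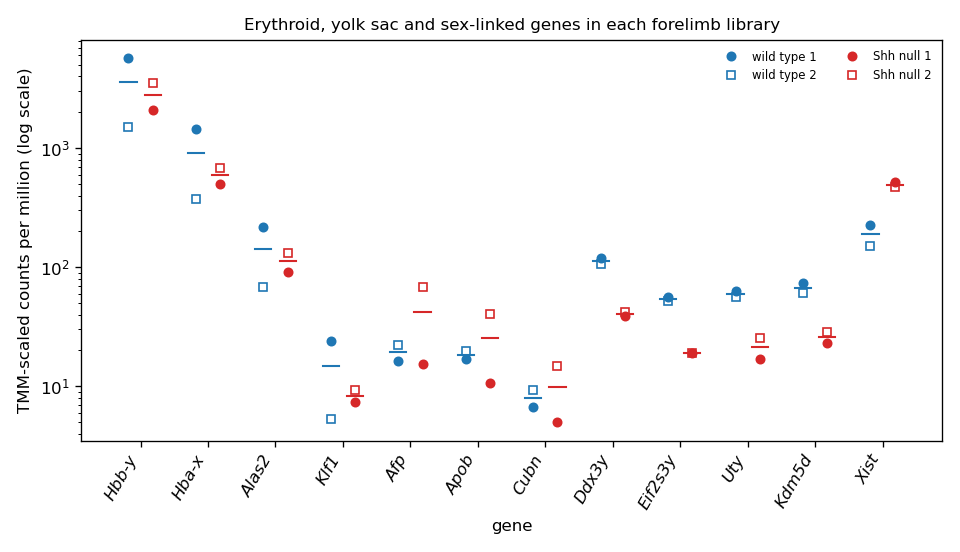
CPM in each of the 4 libraries (vertical log axis) for 4 erythroid genes, 3 yolk sac genes and 5 sex-linked genes (horizontal axis), with circles for replicate 1, open squares for replicate 2 and a bar at each group mean. Hbb-y lies at 5694 CPM in wild type 1 and 1492 CPM in wild type 2, whereas Ddx3y separates the groups, at 119 and 106 CPM against 39.1 and 42.3 CPM.

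Over all 13224 tested genes, limma called 328 (2.48%), of which 164 were higher and 164 lower in the Shh null forelimbs. Of these, 69 were at least 2-fold higher and 73 at least 2-fold lower in mean CPM, and at 4-fold the numbers were 7 and 27, so that changes of 4-fold were mostly losses. Outside the lists, the steepest losses included Osr2 (16.5-fold, 8.75 ± 1.08 to 0.529 ± 0.425 CPM, SD, n = 2), Mamdc2 (13.2-fold, 7.92 ± 0.76 to 0.60 ± 0.38 CPM) and the histone gene Hist1h2ab (5.74-fold, 213 ± 8.42 to 37.1 ± 6.11 CPM), whose reads can be shared with near-identical histone copies. The fold of Osr2 (counting interval 10.9 to 25.6) was 38.3 without Shh null 1 and 10.55 without Shh null 2, and that of Mamdc2 (counting interval 9.26 to 21.1) was 23.9 without Shh null 2. The largest fitted gain of any called gene was that of Nr1h5, a nuclear receptor gene (chromosome 3, 102939658 to 102964133). It was read at 0 and 0.33 CPM in wild type and at 21.3 and 19.1 CPM in Shh null, a ratio of 157.6 over the pooled reads (95% counting interval 72.1 to 431; log2 fold change 4.20 ± 0.20 SE, adjusted p = 5.77e-06). The ratio of mean CPM was 61.2 without wild type 1. Rprm (3.50-fold, 3.64 ± 0.536 to 12.7 ± 4.96 CPM), Angptl1 (3.05-fold, 4.88 ± 1.05 to 14.9 ± 1.46 CPM), Col1a1 (2.60-fold, 13.7 ± 1.84 to 35.5 ± 13.2 CPM), the glutamate receptor gene Gria2 (2.39-fold, 39.3 ± 1.05 to 94.1 ± 9.29 CPM) and Col6a3 (2.33-fold, 11.9 ± 0.916 to 27.8 ± 3.98 CPM) followed. All 328 called genes had non-overlapping groups, as did 50.2% of all tested genes. Chance gives 33.3%. The counts of genes higher and lower were 15 and 41 without Shh null 1, 39 and 60 without Shh null 2, 386 and 416 without wild type 2, and 271 and 188 without wild type 1. The calls of Rprm, Angptl1 and Col6a3 ended without Shh null 1 (adjusted p = 0.126, 0.0897 and 0.0931) and that of Col1a1 without Shh null 2 (0.0893). Without genes of chromosomes X and Y or of unknown chromosome, 164 genes were higher and 157 lower.

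The authors' deposited table of their own comparison listed 17712 genes, and 710 of them had a false discovery rate under 0.05, 412 higher and 298 lower in Shh null. All 328 genes called here were among the calls of the authors' deposited table, in the same direction, which is a comparison of methods on the same libraries and not an independent measurement. Of the calls in the authors' deposited table, 660 were tested here, 50 lay below the filter on low values, and 332 were tested and not called. Across genes, the log2 fold changes correlated with those of the authors' deposited table at r = 0.966. Restricted to changes of at least 2-fold, the authors' deposited table held 230 tested calls, of which 142 were called here.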

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

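The crossed pairing, the erythroid covariate and the removal of sex chromosomes were chosen after the data were seen. The counts of genes called, 164 higher and 164 lower, stayed within 1.5 times under both pseudocounts, the stricter filter, both other scalings, edgeR, the block, the 1.5-fold requirement and the removal of sex chromosomes. With no filter 79 and 91 genes were called, without the limma trend 108 and 99, and with DESeq2 253 and 273. Leaving out 1 library gave 15 to 386 higher and 41 to 416 lower, the lone library of a group being assumed to vary like the other group. The erythroid covariate gave 426 and 368. The cause was not tested for these, beyond the fewer samples. Of the main calls, 0 changed sign under any of these settings. All of them had non-overlapping groups, which fixes the sign for the pseudocounts, filters, trend, block, crossed pairing and left-out libraries. Same-numbered libraries did not deviate together (r = −0.20 across genes), so the numbers were not taken to pair them: with replicate number as a block 220 and 176 genes were called, and a crossed pairing gave 641 and 745. The log2 fold change of Shh was −1.71 (without wild type 2) to −1.24 (without wild type 1) over the left-out libraries, and it lost its call without either Shh null library. Of 50 named genes called, 23 kept their call without any 1 library; 6 lost it with quantile normalization, 2 with the replicate block (Dusp6, adjusted p = 0.07, and Ccne1, 0.0527), and 0 with either pseudocount or the median-ratio scaling. Of the named genes not called, 5 gained a call with the replicate block (Aldh1a2 0.0455, Axin2 0.0173, Isl1 0.0207, Krt15 0.00758 and Wnt6 0.0109), 8 without wild type 1, 5 without wild type 2 and 0 without either Shh null library. Of 13 gene lists passing, 0 passed with an estimated correlation and 2 in the fry test for one direction, whose null is another one, while 18 passed in the fry test for either direction, 6 of them new and only the WNT list lost; with the replicate block the trunk mesoderm list passed too (adjusted p = 0.046); 12 to 17 passed without 1 library, where the erythroid list, lower but not called, turned higher without wild type 1 (adjusted p = 1.83e-09; range 1.23e-18 to 0.834 over the libraries). Sign changes of results never called were not counted. With calls of at least 2-fold only, the overlap with the authors' deposited table was 142 genes.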

Other observations

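The gene families and sets in the next paragraph, and all tests in this part, were chosen after the data were seen.

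Several collagen genes were called higher in the Shh null forelimbs. Of 35 tested collagen genes 6 were called higher, 0 lower and 29 were not called, and 32 had a positive log2 fold change; Col1a2, a chain of type I collagen, rose from 425 ± 63.3 to 922 ± 188 CPM (SD, n = 2) and Col17a1 from 8.51 ± 1.52 to 17.7 ± 0.652 CPM (camera over 7 added sets, adjusted p = 2.03e-10, and adjusted p = 0.179 with an estimated correlation). All 7 tested HoxB genes and all 6 tested HoxC genes had positive log2 fold changes under the deposited scaling, with Hoxb9, Hoxb7 (1.77 ± 0.374 to 4.30 ± 0.452 CPM) and Hoxc6 (13.8 ± 2.56 to 24.6 ± 3.28 CPM) called (adjusted p = 1.05e-05 and 0.000372, and 0.185 and 0.151 with an estimated correlation). In the other direction, 30 of 30 tested ribosome biogenesis genes had negative log2 fold changes and 5 were called lower, among them Nop2 (176 ± 0.686 to 127 ± 4.39 CPM) and Heatr1 (205 ± 7.26 to 146 ± 12.9 CPM; set adjusted p = 1.4e-14, and adjusted p = 0.15 with an estimated correlation). Of 16 serine and one-carbon enzyme genes 4 were called lower, Mthfd2 (55.9 ± 1.08 to 34.7 ± 1.07 CPM) and Gldc (46.1 ± 2.17 to 23.2 ± 6.59 CPM) among them (set adjusted p = 2.23e-05, and adjusted p = 0.15 with an estimated correlation). The median log2 fold change of each of these sets kept its sign under median-ratio and quantile scaling. The signalling genes Wnt5a (89.0 ± 1.05 to 53.1 ± 1.90 CPM) and Fgf10 (27.5 ± 3.78 to 14.4 ± 0.29 CPM) and the oxidase gene Cyp1b1 (18.0 ± 0.449 to 7.09 ± 1.17 CPM) were called lower.

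The fall of the Y-linked genes with the rise of Xist is a pattern that a different sex makeup of the groups may account for: the largest of the 4 Y-linked ratios was only 1.11 times the smallest, as one lower share of male tissue requires, and no biological explanation was tested. The 4 X-linked partners of Y-linked genes gave 0 calls in limma, edgeR and DESeq2, 0 at an unadjusted p under 0.05, and a median log2 fold change of 0.09. Sex makeup is unlikely to account for 24 of the 311 autosomal calls, 22 lower and 2 higher. Each changed in every pair of libraries by more than any Y-linked gene fell (3.71-fold) or Xist rose (3.45-fold). These bounds are the most that a gene used in 1 sex only can change. Gli1, Ptch1, Hoxd13, Hand2, Grem1 and Fgf4 are among the 24. Counting error was not allowed for, and Hand2 and Pax1 passed their bounds only narrowly. For the other 287 autosomal calls, genotype and sex makeup cannot be told apart, since the groups differ in both in all 4 libraries.

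Libraries of a group were unequal in RNA of other tissues, Hbb-y being at 5694 and 1492 CPM in wild type and at 2078 and 3509 CPM in Shh null. A list of yolk sac genes was higher in Shh null 2 than in Shh null 1 for 10 of 10 tested genes, 6 of them at least 2-fold, with Afp at 68.8 and 15.3 CPM and Apob at 40.5 and 10.7 CPM; 1 of the 10 was called between the genotypes, and the set was higher in Shh null (adjusted p = 0.00415, and adjusted p = 0.479 with an estimated correlation). With the mean erythroid level as a covariate, 328 of 328 calls remained in the same direction. The crossed pairing of replicates kept 328 as well. It groups wild type 1 with Shh null 2, in each group the library richer in erythroid RNA. It is therefore close to the covariate and not a separate check. The erythroid level varied mainly within groups, so the covariate cannot decide whether erythroid RNA is a source of the calls. Without the library rich in yolk sac transcripts, the median ratio of log2 fold changes over the calls was 1.05. It was 0.965 without wild type 1. Called genes differ little within groups, which holds such a ratio near 1, so it cannot decide on yolk sac RNA either. Why libraries described as technical replicates differ in these tissues stays open.

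Hist1h2ab was the only called gene of 59 tested histone cluster genes. A poorer recovery of histone transcripts in the Shh null libraries as a whole is argued against by the other 58, whose median log2 fold change was −0.25 and lowest −1.30, with 0 called by limma and edgeR, 1 by DESeq2 and 6 at an unadjusted p under 0.05. A transfer of its reads to 1 other Hist1h2a copy is argued against too, since the largest gain of any of 9 such genes was 15 CPM between the lower libraries of the groups and 35.2 CPM in any pair of libraries, against at least 166 CPM lost. A spread over several copies may still contribute: the summed value of the other copies was 1299 and 716 CPM in wild type and 699 and 842 CPM in Shh null, so that the largest rise, 126 CPM, is within the difference between libraries of a group. A variant in this outbred stock, or reads dropped because they match several copies, was not tested.

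Within 20 Mb of Shh on chromosome 5, 13 of 192 tested genes other than Shh were called (6.77%), against 2.37% of other autosomal genes (Fisher's exact test, two-sided, p = 0.000868, with neighbouring genes not independent). Nr1h5, on another chromosome, had no read in wild type 1 and 0.33 CPM in wild type 2, against 21.3 and 19.1 CPM in Shh null.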
